A study of Mus musculus with 4 samples.

How the data were processed

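Basal interfollicular cells expressing SmoM2 were compared with and without Sox9. Per the labels' protocols, mice received 2.5 mg of tamoxifen on each of 10 consecutive days, tail epidermis was taken 9 weeks after the first dose and dissociated with trypsin, and cells positive for integrin alpha 6 and negative for CD34 were sorted. Total RNA (100 ng per sample) with spiked bacterial control transcripts was amplified, labelled with biotin and hybridised to Affymetrix 3' expression arrays. There were 4 arrays, 2 per genotype.

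The values deposited by the authors are log2 signals, 1 per probe set and array. The normalization and summary method are not given in the sources used here. R 2.14.0 is named in the submitters' processing notes, without its role. The log2 scale was read from the range of the values, whose medians lay between 5.45 and 5.48 on the 4 arrays, and they were used as deposited. The arrays had nearly equal medians and quartiles, so a change shared by most genes could have been removed before deposit and would not be seen. Arrays give no read depth, so the number of arrays limits the precision.

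The table held 45101 probe sets, of which 64 were control probe sets. The platform annotation listed 35890 probe sets, with 1 gene symbol for 34945 and several for 932, and a further 9160 were not listed and are unnamed here. Symbols were updated through the entrez ID for 34741 probe sets. Probe sets with several symbols or none, and control probe sets, were left out of the gene-level tests. Where a gene had several probe sets, the one with the highest mean over all 4 arrays stood for it, which gave 18193 genes, and no named gene had another probe set called in the opposite direction. Sox9 was also read at each of its probe sets.

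Sox9cKO arrays were compared with SmoM2 arrays in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with the default prior, no covariate, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Each test had 7.17 degrees of freedom, prior included. Genes were also counted whose mean differed at least 2-fold with arrays of the genotypes not overlapping. Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 34 lists with at least 5 measured members. The share of called genes in each list was compared with all other genes by Fisher's exact test, two-sided and adjusted over the lists, a test chosen after seeing the data. It treats genes as independent, although all calls come from the same 4 arrays, and does not allow for signal level.

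The tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The 35 lists held 705 entries (657 different genes), of which 660 (613) were measured, and some genes stand in several lists. They covered Hedgehog pathway and target genes, Wnt targets, Notch, TGF-beta and BMP, EGFR and MAPK feedback, Sox family, cartilage targets of Sox9, bulge stem cells, embryonic hair follicle progenitors, interfollicular basal cells, suprabasal differentiation, hyperproliferation and wound genes, hair keratin and tail scale genes, G2/M and mitosis, DNA replication, p53 and senescence, immediate early and stress genes, basement membrane and matrix, matrix remodelling enzymes, adhesion and junctions, cytoskeleton and migration, EMT regulators, interferon response, and markers of sebocytes, inner root sheath and hair cortex, melanocytes, Merkel cells, Langerhans and myeloid cells, T cells, fibroblasts, endothelium, smooth muscle and pericytes, skeletal muscle and erythroid cells. A list of sex-linked genes served as a sample check and was not tested. Named are every Sox9 probe set, the 12 genes of largest log2 change in each direction that passed the test with arrays not overlapping (symbols that are only clone or model identifiers passed over), up to 4 members of each list by smallest p with further members where they describe it, and genes for the sample checks. Which further members to name was settled after the results were seen, and 12 genes named at first were taken out to shorten the text, some of them because their calls were lost when an array was left out.

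The procedure was tested on simulated data made from the means of the 18193 genes and the fitted prior of their variance, with 50 genes changed at each of 4 fold sizes in a simulated Sox9cKO against SmoM2 comparison. It recovered 4% of genes changed 1.5-fold, 44% of those changed 2-fold, 96% of those changed 4-fold and 98% of those changed 8-fold, with 10 false calls among 131 and 0 of wrong sign. The simulated spread followed the prior that the test assumes, so a low share of false calls was partly built in. A smaller share of genes was changed than was called in the data, so the recovered shares may not carry over. camera with the preset correlation called the 1 list moved in the simulation and 0 others, and did not call it with an estimated correlation. Simulated genes varied independently, whereas the correlation estimated in the data was 0.77 for the G2/M list. The simulation therefore cannot show whether the preset correlation gives false list calls where genes vary together.

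Alternatives were the mean of a gene's probe sets, every probe set on its own, leaving out probe sets with identifiers ending in _x_at or _s_at, leaving out the dimmer part of the genes by mean signal, quantile normalization again, equal array medians, an intensity trend with robust prior, a replicate block, leaving out each array in turn, a 1.5-fold minimum, camera with an estimated correlation, and fry. An alternative pseudocount did not apply to log2 values.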

Results

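Gene expression was measured on Affymetrix 3' arrays in basal cells sorted from mouse tail epidermis. SmoM2 is a constitutively active form of the Hedgehog signal transducer Smoothened, and K14CreER is a tamoxifen-dependent Cre recombinase expressed in basal keratinocytes. Of the 4 arrays, 2 came from SmoM2-expressing cells with intact Sox9 (the SmoM2 group) and 2 from SmoM2-expressing cells in which Sox9 was conditionally deleted (the Sox9cKO group), all 9 weeks after the first tamoxifen dose. The sort took cells positive for integrin alpha 6, a surface marker of basal keratinocytes, and negative for CD34, a marker of bulge hair follicle stem cells. The labels do not say how many animals each replicate came from. Y-linked signal, given below, differed between the replicates of each genotype, so they were not repeats of 1 sample, and the p-values measure the spread between these samples. With 2 arrays per group, the number of arrays limits the precision of every value.

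The median signal was 5.48 and 5.47 on the log2 scale in SmoM2 replicates 1 and 2, and 5.45 and 5.47 in Sox9cKO replicates 1 and 2. Across probe sets, Pearson's r was 0.991 within the SmoM2 group and 0.991 within the Sox9cKO group, and lay between 0.978 and 0.980 for arrays of different groups, with probe sets not being independent replicates. Y-linked genes (Eif2s3y, Kdm5d and Uty) had log2 signals of 6.74 to 9.48 in SmoM2 replicate 2 and Sox9cKO replicate 1, against 3.23 to 3.62 in the other arrays, so each group held 1 array with and 1 without Y-linked signal. Xist, which is transcribed from the inactive X chromosome, measured 11.76 and 8.11 in SmoM2 replicates 1 and 2 and 10.92 and 11.97 in Sox9cKO replicates 1 and 2, and was thus present beside Y-linked signal. The spiked labelling controls averaged 9.14 and 8.47 in the SmoM2 arrays and 9.34 and 7.78 in the Sox9cKO arrays, lower in replicate 2 of each genotype. The signal of 18S rRNA followed the same order, at 11.24 and 10.09 against 11.12 and 9.87. The 3' minus 5' difference of Actb, a sign of RNA degradation, was 0.74 and 0.46 in the SmoM2 arrays and 0.75 and 0.52 in the Sox9cKO arrays.

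**Figure D1:**
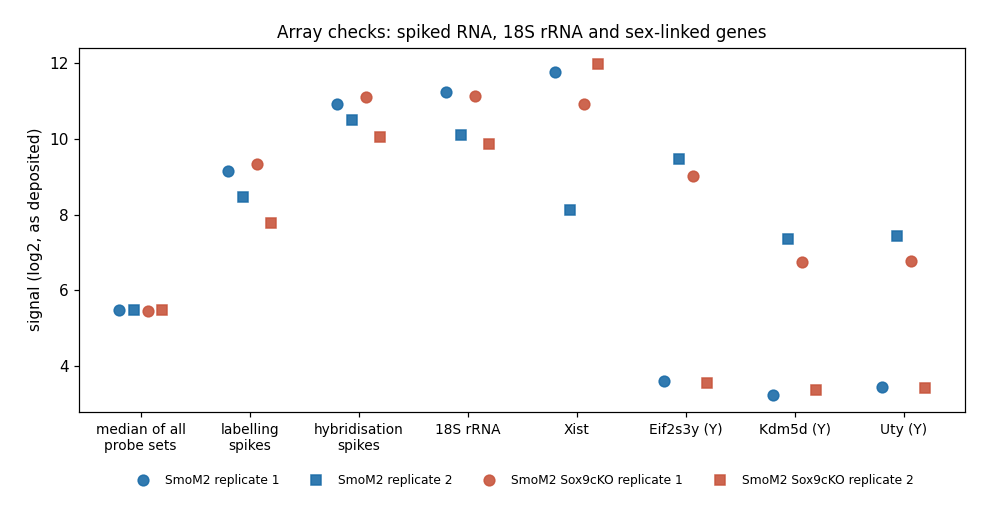
Log2 signal of array checks (vertical axis) on each of the 4 arrays, coloured by genotype with circles for replicate 1 and squares for replicate 2; each point is 1 array and no error is drawn. Medians of all probe sets lie between 5.45 and 5.48, spiked RNA and 18S rRNA are lower in replicate 2 of both genotypes, and Y-linked genes are at 6.74 or above in 1 array per genotype and at 3.62 or below in the other.

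The deleted gene was read first. Sox9, a transcription factor of hair follicle and cartilage cells, fell by 3.89 on the log2 scale (SE 0.32) at the probe set that was brightest for it in the SmoM2 arrays, from 10.12 ± 0.14 to 6.23 ± 0.74 (SD, n = 2 each), a 14.9-fold difference with adjusted p = 0.00159 when every probe set was tested by limma. The probe set with the highest mean over all 4 arrays, and therefore the value used for the gene, read 9.02 ± 0.36 in SmoM2 and 8.27 ± 0.29 in Sox9cKO, a log2 change of -0.75 (SE 0.22) that did not pass the test (adjusted p = 0.108 among genes and 0.143 among probe sets). The remaining probe set was dim, at 4.37 ± 0.21 and 3.96 ± 0.14 (adjusted p = 0.298). The place of these probes relative to the deleted exons is not given in the sources used here, so a probe set outside the deleted part would check nothing. With the mean of the 3 Sox9 probe sets in place of the brightest, the change was -1.68 (adjusted p = 0.00256), and without SmoM2 replicate 2 the gene value was -0.50 (adjusted p = 0.387).

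Loss of Sox9 in SmoM2-expressing basal cells went with higher expression of 484 genes and lower expression of 642, together 1126 of 18193 genes tested, at an adjusted p under 0.05 (limma). Of these, 270 were at least 2-fold higher and 394 at least 2-fold lower. By a count that rests on no test, 318 genes were at least 2-fold higher and 439 at least 2-fold lower with the arrays of each genotype not overlapping, 757 in all. Arrays did not overlap at any fold for 47.9% of genes, where chance gives 33.3%. Fewer genes were called with a SmoM2 array left out than with a Sox9cKO array left out. In those fits the lone array was assumed to vary like the other group. The spread then came from the intact pair alone, so this difference does not show on which arrays the calls rest. An exact permutation test of a single gene cannot go below p = 0.333 with 2 arrays against 2, so all calls rest on the spread that limma shares across genes.

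The 12 genes of largest increase included keratins, secreted signals and matrix genes. Prr9, a proline-rich gene of the epidermal differentiation complex, rose by 6.28 (SE 0.16), from 6.43 ± 0.08 to 12.72 ± 0.25 (SD, n = 2), a 77.9-fold difference with adjusted p = 2.56e-05. Slc15a2, an oligopeptide transporter, rose 49.1-fold (log2 5.62, SE 0.22, adjusted p = 0.000135). Krt75, a keratin of the companion layer of the hair follicle, rose 37.3-fold (log2 5.22, SE 0.47, adjusted p = 0.00126), and the epithelial keratin Krt24 rose by 3.99. Among secreted factors, the cytokine Tslp rose 31.6-fold (log2 4.98, SE 0.29, adjusted p = 0.000318), the chemokine Ccl1 by 3.85 and the hormone stanniocalcin (Stc1) by 3.71. The matrix glycoproteins Efemp1 and Dcn (decorin) rose by 4.24 and 3.66. Maob, a mitochondrial amine oxidase, rose by 3.88, Clca3a2 by 3.81 and Jakmip2 by 3.70. The SmoM2 signal of Jakmip2, 3.41, lay within the range of absent Y-linked transcripts and those of Tslp, 3.69, and Maob, 3.80, near it, so the sizes and ranks of their changes are not exact. The adjusted p values of these last 8 genes lay between 0.000135 and 0.00398, and Ccl1 missed the threshold with an intensity trend and robust prior (adjusted p = 0.0653). With the mean of a gene's probe sets the changes were smaller, at 2.06 for Slc15a2, 1.82 for Stc1 and 1.27 for Jakmip2, and Dcn was then 5.64-fold higher, against 12.6-fold. No other probe set of Slc15a2, Stc1 or Jakmip2 was called. Leaving out Sox9cKO replicate 1 or 2 gave 22.0-fold and 63.0-fold for Krt75, 25.7-fold and 8.06-fold for Ccl1, and 21.4-fold and 9.18-fold for Clca3a2.

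The 12 genes of largest decrease included Defb3, S100a8, S100a9 and Foxc1. Defb3, a beta-defensin, fell by 4.73 (SE 0.31), from 9.02 ± 0.74 to 4.29 ± 0.16 (SD, n = 2), a 26.5-fold difference with adjusted p = 0.000446. S100a8 and S100a9, whose products form calprotectin, fell (log2 changes of -3.56 and -3.71) from signals of 13.26 and 13.15 in SmoM2. Tnfaip2, a TNF-induced gene, fell by 4.28 (SE 0.18, adjusted p = 0.000135), and the acute-phase protein gene Orm1 and the protease inhibitor gene Spink12 changed by -3.95 and -4.10. Gpx2, a glutathione peroxidase, changed by -3.78, the natriuretic peptide gene Nppb by -3.74 and the cationic amino acid transporter Slc7a2 by -3.54. Foxc1, a transcription factor of hair follicle stem cells, changed by -3.66, the basement membrane gene Frem2 by -3.57 and the scaffold gene Dlgap1 by -3.48. The 12 genes had adjusted p values of 0.00253 or lower. With the mean of a gene's probe sets the changes were smaller, at -2.13 for Tnfaip2 (-2.33 without _x_at and _s_at probe sets), -1.47 for Slc7a2 and -1.91 for Dlgap1.

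**Figure D2:**
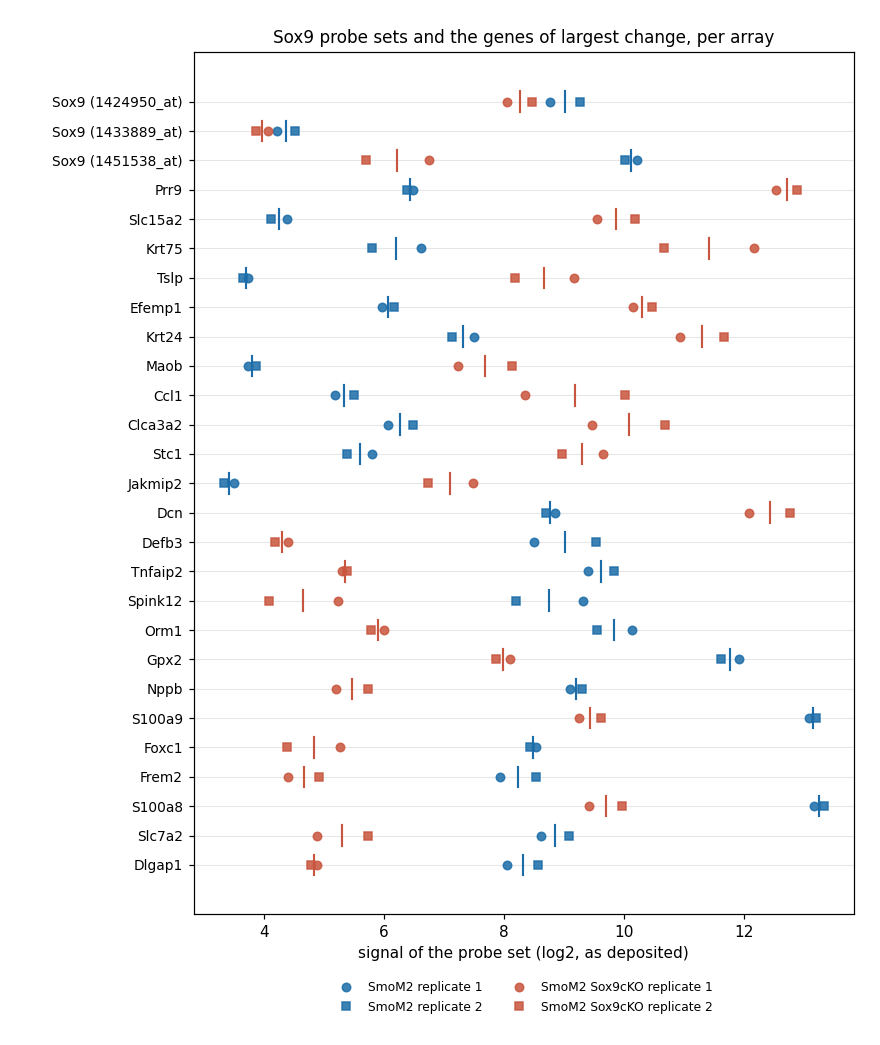
Log2 signal (horizontal axis) of the 3 Sox9 probe sets and of the 12 genes of largest increase and 12 of largest decrease, with 1 point per array (blue SmoM2, red Sox9cKO, circles replicate 1, squares replicate 2) and a vertical bar at each group's mean of 2 arrays. The Sox9 probe set brightest in SmoM2 lies at 10.12 in SmoM2 and 6.23 in Sox9cKO on average, and Prr9 at 6.43 and 12.72.

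Genes of the hair follicle bulge, a stem cell niche, fell as a group, with 10 of 22 measured members lower and 1 higher (adjusted over the list alone, 11 lower and 1 higher). The median log2 change was -0.88 and camera gave adjusted p = 1.18e-07, against adjusted p = 0.726 with an estimated correlation. Foxc1 was the largest change, and Lrig1, a stem cell regulator, changed by -1.61 (SE 0.18), the Wnt pathway gene Dkk3 by -1.35 (SE 0.17) and the growth factor Fgf1 by -1.19 (SE 0.14). The list's median was -0.56 without SmoM2 replicate 2, and Lrig1 was at -0.98 with the mean of its probe sets. The member that rose was the transcription factor Lhx2, by 0.79, whose adjusted p of 0.0238 became 0.133 and 0.103 without SmoM2 replicate 1 or 2 and 0.102 without Sox9cKO replicate 1.

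The embryonic hair follicle progenitor list moved both ways, with 6 of 23 measured members higher and 7 lower (8 and 9 adjusted over the list alone). Cux1 and Dlx2, homeobox transcription factors, rose by 2.65 and 2.05, while Foxc1, the Wnt inhibitor Wif1 and the adhesion molecule Ncam1 fell (log2 changes of -3.66, -3.21 and -2.30). Wif1 missed the threshold with an intensity trend and robust prior (adjusted p = 0.0675), and its log2 changes were -3.80 and -2.61 without Sox9cKO replicate 1 or 2. camera found no shift (adjusted p = 0.940; the median change was 0.02, the mean -0.17), but 56.5% of members were called against 6.19% of all genes. Fisher's exact test, chosen after seeing the data, gave an adjusted p of 3.97e-09 for that share. It treats genes as independent, whereas the correlation estimated between members of this list was 0.24. Brighter genes were also called more often, at 801 of 9096 with dim genes left out against 1126 of 18193. This list averaged 8.11 to 8.45 per array. The Fisher p-values of this and the other lists may therefore overstate the evidence. With dim genes left out, camera called the list lower (median -0.57, adjusted p = 0.0467, against adjusted p = 0.797 with an estimated correlation), and Ncam1 was at -1.12 with the mean of its probe sets.

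Mitotic genes rose as a group while DNA replication genes did not pass. Of 29 measured members of the G2/M list, 12 rose and none fell (24 higher adjusted over the list alone), and all 29 had a positive log2 change with a median of 0.68. camera gave adjusted p = 9.97e-16, against adjusted p = 0.726 with an estimated correlation. The spindle motor Kif11 rose by 0.98 (SE 0.13), the proliferation marker Mki67 by 0.94 (SE 0.14) and the spindle gene Nusap1 by 1.00 (SE 0.17). Without SmoM2 replicate 2 the adjusted p of Kif11, Mki67 and Nusap1 was 0.0519, 0.0847 and 0.0836, that of Mki67 was 0.0527 without SmoM2 replicate 1, and that of Nusap1 was 0.0507 without Sox9cKO replicate 2. With the mean of a gene's probe sets the adjusted p was 0.0556 for Kif11 and 0.0644 for Nusap1. Of 29 measured DNA replication genes none was called by limma (none adjusted over the list alone), the median was 0.14 and 24 were positive, and camera gave adjusted p = 0.0978. Pola1, the DNA polymerase subunit with the smallest p, changed by 0.46 (adjusted p = 0.110), or 0.31 with the mean of its probe sets. The replication list passed without SmoM2 replicate 1 (adjusted p = 0.0292, against 0.756 with an estimated correlation) and without Sox9cKO replicate 2 (adjusted p = 0.0280, against 0.946 with an estimated correlation). The replication list's median was only 0.07 without SmoM2 replicate 2 and 0.03 without Sox9cKO replicate 1. A difference between the G2/M and replication lists was not tested.

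Genes of the inner root sheath and hair cortex, differentiated layers of the hair follicle, rose together. Of 14 measured members 8 rose and none fell (10 higher adjusted over the list alone), with a median change of 1.18 and camera adjusted p = 6.96e-07, against adjusted p = 0.726 with an estimated correlation. The keratin Krt25 rose by 3.24 (SE 0.25), trichohyalin (Tchh) by 1.78 (SE 0.18) and the transcription factor Gata3 by 1.11 (SE 0.14). The sebocyte list went the other way, with 3 of 14 measured members lower and none higher (7 lower adjusted over the list alone), a median of -0.82 and camera adjusted p = 3.72e-05 (adjusted p = 0.726 with an estimated correlation). Cidea and Plin2, lipid droplet genes, changed by -2.29 (SE 0.22) and -1.18 (SE 0.17), and the fatty acid elongase Elovl5 fell by 0.77 (SE 0.18, adjusted p = 0.0498). The adjusted p of Elovl5 was 0.104 and 0.240 without SmoM2 replicate 1 or 2 and 0.190 without Sox9cKO replicate 1. The sebocyte list averaged 8.27 in SmoM2 replicate 1 and 7.62 in SmoM2 replicate 2, against 7.21 and 7.05 in the Sox9cKO arrays, and missed the threshold with dim genes left out (median -0.25, adjusted p = 0.102). The list's median was -0.43 without SmoM2 replicate 1 and -0.48 with every probe set. Of 10 measured hair keratin and tail scale genes none was called (none adjusted over the list alone, median 0.22, camera adjusted p = 0.321). The median of these genes was 0.43 and 0.06 without SmoM2 replicate 1 or 2, and 0.12 and 0.10 without Sox9cKO replicate 1 or 2.

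Hyperproliferation and wound genes fell as a group. Of 17 measured members 5 fell and none rose (9 lower adjusted over the list alone), with a median of -0.66 and camera adjusted p = 1.77e-08, against adjusted p = 0.726 with an estimated correlation. These were Defb3, S100a8, S100a9, the iron-binding antimicrobial gene Lcn2, which fell by 1.75 (SE 0.14), and the growth factor Hbegf, which fell by 1.41 (SE 0.16). The stress keratins of the list did not pass, with changes of -0.61 for Krt16 (adjusted p = 0.111) and -0.30 for Krt6a (adjusted p = 0.361). The list's median was -1.01 without SmoM2 replicate 1 and -0.39 without SmoM2 replicate 2, and without the latter Krt16 was at -0.39 and Krt6a at -0.20.

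Basal keratinocyte genes fell as a group. Of 18 measured interfollicular basal genes 3 fell and none rose (5 lower and 1 higher adjusted over the list alone), with a median of -0.42 and camera adjusted p = 0.00259, against adjusted p = 0.726 with an estimated correlation. The laminin genes Lamb3 and Lama3 fell (log2 changes of -1.25, SE 0.19, and -1.12, SE 0.19), and the integrin gene Itgb6 fell by 1.03 (SE 0.17). The basal keratin Krt14 changed by -0.41 (adjusted p = 0.209) and Itga6, the sorting marker, by -0.45 (adjusted p = 0.192), or -0.27 without SmoM2 replicate 2. Without SmoM2 replicate 2 the adjusted p was 0.0704 for Lamb3, 0.0753 for Lama3, 0.0736 for Itgb6 and 0.106 for the list, whose median was then -0.14, without SmoM2 replicate 1 it was 0.0941 for Itgb6, and without Sox9cKO replicate 1 it was 0.0590 for Lama3. The list's median was -0.26 with every probe set, and with the mean of a gene's probe sets Lama3 was at -0.56 (adjusted p = 0.0915) and Itgb6 at -0.72 (adjusted p = 0.0636).

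The suprabasal differentiation list moved both ways, with 5 of 29 measured members higher and 4 lower (8 and 7 adjusted over the list alone; camera adjusted p = 0.682, median 0.08). Loricrin (Lor) rose by 1.56, Lce1a1 by 2.17, filaggrin (Flg) by 1.82, the transglutaminase Tgm3 by 1.23 and the desmosomal cadherin Dsg1a by 1.87. Cnfn, Serpinb3a, the protease inhibitor Spink5 and the transcription factor Grhl3 fell (log2 changes of -1.88, -1.68, -2.77 and -1.05). The share called, 31.0%, exceeded that of other genes (Fisher's exact test, adjusted p = 0.000284). Without SmoM2 replicate 2 the adjusted p was 0.163 for Flg, 0.0605 for Cnfn, 0.121 for Serpinb3a, 0.171 for Spink5 and 0.168 for Grhl3. Without SmoM2 replicate 1 it was 0.0886 for Flg, 0.0927 for Serpinb3a and 0.0799 for Grhl3. It was 0.0972 for Spink5 without Sox9cKO replicate 1 and 0.0850 for Grhl3 without Sox9cKO replicate 2, and Spink5 (adjusted p = 0.297) and Flg (adjusted p = 0.0508) missed the threshold with an intensity trend and robust prior, as Spink5 did with the mean of a gene's probe sets (adjusted p = 0.0591). Spink5 was 6.83-fold lower with all arrays, and leaving out SmoM2 replicate 1 or 2 gave log2 changes of -3.58 and -1.96, and Sox9cKO replicate 1 or 2 -2.06 and -3.49.

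Basement membrane and matrix genes fell as a group by a small median. Of 30 measured members 5 fell and none rose (6 lower and 2 higher adjusted over the list alone), with a median of -0.11 and camera adjusted p = 0.0143, against adjusted p = 0.726 with an estimated correlation, 0.124 without SmoM2 replicate 2 and 0.160 with dim genes left out. The median was -0.18 without SmoM2 replicate 1, -0.19 without Sox9cKO replicate 2 and -0.06 with every probe set. Frem2 and Fras1, which act in the same basement membrane complex, changed by -3.57 (SE 0.25) and -1.35 (SE 0.17), Egfl6 by -3.07 (SE 0.20), to a signal of 3.75 near that of absent transcripts, and the collagen genes Col5a2 and Col16a1 by -2.69 (SE 0.21) and -1.63 (SE 0.13). Of 25 measured matrix remodelling enzymes and their inhibitors 2 rose and 4 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.369, median -0.08, Fisher's exact test adjusted p = 0.0151). The protease Adamts9 and the plasminogen activator Plat rose by 1.34 and 1.45, while Adamts5, Timp2, Sulf1 and Adamts1 fell (log2 changes of -1.94, -1.62, -1.07 and -0.93). Without SmoM2 replicate 1 or 2 the adjusted p was 0.0558 and 0.0945 for Timp2, 0.0901 and 0.0825 for Sulf1, and 0.0941 and 0.192 for Adamts1, which was at 0.118 without Sox9cKO replicate 2. Sulf1 was at -0.50 (adjusted p = 0.101), Timp2 at -0.96 and Adamts5 at -1.34 with the mean of a gene's probe sets, and Timp2 had adjusted p = 0.0593 without _x_at and _s_at probe sets.

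Cytoskeletal and adhesion genes changed in both directions. Of 33 measured cytoskeleton and migration genes 2 rose and 3 fell (3 and 8 adjusted over the list alone), with a median of -0.15 and camera adjusted p = 0.0268, against adjusted p = 0.726 with an estimated correlation. The neuronal tubulin Tubb3 changed by -3.08 (SE 0.22), Cdc42ep3 by -1.60 (SE 0.20) and Palld by -0.82, while the calponin Cnn3 rose by 2.31. The list had adjusted p = 0.110 without SmoM2 replicate 2, 0.274 without Sox9cKO replicate 2 (median -0.07), 0.0782 with dim genes left out and 0.0575 without _x_at and _s_at probe sets. Without SmoM2 replicate 1 or 2 the adjusted p was 0.218 and 0.154 for Palld and 0.126 and 0.176 for Cnn3. Palld was at 0.158 without Sox9cKO replicate 2. With an intensity trend and robust prior Cnn3 (adjusted p = 0.204) and the cadherin Cdh11 (adjusted p = 0.218) missed the threshold, and without Sox9cKO replicate 1 the rise of Cnn3 was 2.84-fold, and without Sox9cKO replicate 2 8.67-fold, against 4.96-fold with all arrays. Of 31 measured adhesion and junction genes 1 rose and 5 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.126, median -0.03, Fisher's exact test adjusted p = 0.0366), and the list passed without SmoM2 replicate 1 (adjusted p = 0.0172, against 0.756 with an estimated correlation) and with every probe set (adjusted p = 0.0318, against 0.618 with an estimated correlation). The adhesion and junction list's median was -0.08 without SmoM2 replicate 1 but 0.02 without SmoM2 replicate 2. Dsg1a rose, while Ncam1, the epithelial adhesion gene Epcam, Mcam, Alcam and Cdh11 fell (log2 changes of -2.30, -1.43, -1.14, -1.48 and -2.49). Without SmoM2 replicate 1 or 2 Mcam was at 0.0509 and 0.0591 and Alcam at 0.135 and 0.134, and Cdh11 was at 0.152 without SmoM2 replicate 2 and 0.0935 without Sox9cKO replicate 1. The decrease of Cdh11, 5.60-fold with all arrays, was 9.29-fold and 3.38-fold without SmoM2 replicate 1 or 2, 3.72-fold and 8.45-fold without Sox9cKO replicate 1 or 2, and 3.38-fold with the mean of its probe sets. Cdh11 was the called member of the EMT regulator list (0 higher and 1 lower of 13, 1 and 1 adjusted over the list alone; camera adjusted p = 0.473, and 0.0448 with every probe set, against 0.562 with an estimated correlation).

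The Hedgehog and Wnt lists had called genes in both directions and no shift called by camera. Of 19 measured Hedgehog pathway and target genes 1 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.820, median 0.01, mean -0.14, Fisher's exact test adjusted p = 0.535). The cell cycle gene Ccnd2 rose by 1.75 (SE 0.15) and Sfrp1, a secreted Wnt modulator, fell by 2.35 (SE 0.19). The direct target Gli1 changed by 0.30 (adjusted p = 0.324) and the feedback inhibitor Hhip by -2.39 (adjusted p = 0.0698). For Hhip, 5.24-fold lower with all arrays, leaving out SmoM2 replicate 1 or 2 gave 8.35-fold and 3.29-fold (adjusted p = 0.0910 and 0.312), and leaving out Sox9cKO replicate 1 or 2 gave 2.84-fold and 9.69-fold (adjusted p = 0.155 and 0.00818). Of 19 measured Wnt targets 1 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.940, median 0.02, mean -0.09). The share called, 21.1% against 6.19% of all genes, did not pass (Fisher's exact test, adjusted p = 0.0760, unadjusted p = 0.0268). Tnfrsf19 rose by 1.77, Wif1, Bambi and Myc fell (log2 changes of -3.21, -1.24 and -0.61), and the general target Axin2 changed by 0.47 (adjusted p = 0.156). Tnfrsf19 was at adjusted p = 0.0863 without SmoM2 replicate 2, and Myc was at 0.133, 0.188, 0.144 and 0.126 without each of the arrays in turn (SmoM2 replicates 1 and 2, then Sox9cKO replicates 1 and 2). With the mean of a gene's probe sets Sfrp1 was at -1.27, Tnfrsf19 at 1.04 and Axin2 at 0.14.

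TGF-beta and BMP genes went both ways, with 4 of 22 measured members higher and 3 lower (6 and 5 adjusted over the list alone; camera adjusted p = 0.716, median -0.07). The BMP-responsive genes Id2 and Id3 rose by 1.22 and 1.47, and the ligands Tgfb2 and Bmp4 by 1.77 and 1.43. Tgfb3 and the BMP antagonists Bambi and Grem1 fell (log2 changes of -2.03, -1.24 and -1.90). The share called, 31.8%, exceeded that of other genes (Fisher's exact test, adjusted p = 0.00145), and Bmp4 was at adjusted p = 0.131 without SmoM2 replicate 1 and 0.0593 without Sox9cKO replicate 2.

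The EGFR and MAPK feedback list was called lower by camera, with 4 of 18 measured members lower and none higher (6 lower and 1 higher adjusted over the list alone), a median of -0.17 and camera adjusted p = 0.0244, against adjusted p = 0.786 with an estimated correlation. The genotypes overlapped in the list's mean signal, at 8.51 and 8.94 in SmoM2 replicates 1 and 2 and 8.65 and 8.26 in Sox9cKO replicates 1 and 2. Hbegf changed by -1.41, Phlda1 by -1.39 (SE 0.19), and the MAPK phosphatase genes Dusp4 and Dusp5 by -1.04 (SE 0.14) and -0.66. The list was at adjusted p = 0.541 (median -0.01) without SmoM2 replicate 2 and 0.494 (median -0.03) without Sox9cKO replicate 2, and its median was -0.47 without SmoM2 replicate 1 and -0.50 without Sox9cKO replicate 1. It was at adjusted p = 0.0806 with dim genes left out and 0.0573 (median -0.08) with every probe set. Dusp5 was at 0.164 and 0.191 without SmoM2 replicate 1 or 2, at 0.0569 and 0.192 without Sox9cKO replicate 1 or 2, and at 0.0546 with an intensity trend and robust prior.

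Of 16 measured Sox family genes other than Sox9, 3 fell and none rose (3 lower adjusted over the list alone; camera adjusted p = 0.940, median 0.12, mean -0.12). Sox2 fell by 3.20 (SE 0.26), from 6.76 to 3.56, which lies at the signal of Y-linked genes in arrays without Y-linked signal. Sox13 fell from 7.85 to 6.85 (SE of the change 0.17), and Sox15 fell by 0.76. Without SmoM2 replicate 1 or 2 the adjusted p was 0.111 and 0.0628 for Sox13 and 0.0857 and 0.140 for Sox15, with 0.0623 for Sox13 without Sox9cKO replicate 2 and 0.101 for Sox15 without Sox9cKO replicate 1. Of 18 measured cartilage genes, a list of Sox9 targets in chondrocytes, none was called by limma (none adjusted over the list alone; camera adjusted p = 0.337, median 0.10). Of 17 Notch genes 1 rose, Heyl by 1.08 (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.940, median -0.00916, mean 0.04), with adjusted p of 0.117, 0.127 and 0.0521 for Heyl without SmoM2 replicate 1, SmoM2 replicate 2 and Sox9cKO replicate 1. Of 20 p53 and senescence genes none was called (none adjusted over the list alone; camera adjusted p = 0.820, median 9.65e-05, mean -0.07). Of 22 immediate early and stress genes the heat shock gene Hspa1a rose by 0.98 and the transcription factor Egr2 fell by 1.49 (1 and 3 adjusted over the list alone; camera adjusted p = 0.729), with Hspa1a at adjusted p = 0.142 without SmoM2 replicate 1 and 0.105 without Sox9cKO replicate 2.

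Interferon response genes rose as a group, with 4 of 20 measured members higher and none lower (5 higher adjusted over the list alone), a median of 0.29 and camera adjusted p = 0.0193, against adjusted p = 0.786 with an estimated correlation. Ifit2 and Oas1a rose by 1.51 (SE 0.15) and 1.91 (SE 0.20), Irf7 by 1.07 and Usp18 by 0.95. The list was at adjusted p = 0.0718 (median 0.17) without SmoM2 replicate 2 and 0.271 (median 0.18) without Sox9cKO replicate 2, and its median was 0.52 with dim genes left out. Without SmoM2 replicate 1 or 2 Irf7 was at 0.0899 and 0.0903 and Usp18 at 0.0554 and 0.135, and Usp18 was at 0.0846 without Sox9cKO replicate 2. Langerhans cell and myeloid genes, markers of immune cells outside the sorted population, also rose as a group, with 1 of 22 measured members higher (5 higher and 1 lower adjusted over the list alone), a median of 0.28 and camera adjusted p = 0.00103, against adjusted p = 0.726 with an estimated correlation. The share called, 4.55%, was not above the 6.19% of all genes, and 18 members had a positive change. The list was dim, averaging 5.08 and 4.92 in SmoM2 replicates 1 and 2 and 5.39 and 5.31 in Sox9cKO replicates 1 and 2. These means lay below the array medians of 5.45 to 5.48. With dim genes left out fewer than 5 members remained, so the call of this list could not be retested there. The MHC class II gene H2-Aa rose by 1.87 (SE 0.16), from 5.30 to 7.17 (0.96 with the mean of its probe sets), and the Langerhans cell marker Cd207 changed by 0.48 (adjusted p = 0.236), or 0.27 without SmoM2 replicate 2.

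Fibroblast genes were mixed, with 3 of 19 measured members higher and 2 lower (3 and 3 adjusted over the list alone; camera adjusted p = 0.337, median 0.11, Fisher's exact test adjusted p = 0.0191). Dcn rose by 3.66, Thy1 by 1.99 (SE 0.16) and Col6a3 by 0.70, while Fbln2 and Col5a3 changed by -1.48 (SE 0.14) and -0.88. Col6a3 was at adjusted p = 0.186, 0.0935, 0.0770 and 0.146 without each of the arrays in the same order, and Col5a3 at 0.151, 0.115 and 0.0643 without SmoM2 replicate 2, Sox9cKO replicate 1 and Sox9cKO replicate 2. With the mean of a gene's probe sets Col5a3 was at -0.43 (adjusted p = 0.0996) and Fbln2 at -0.83.

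**Figure D3:**
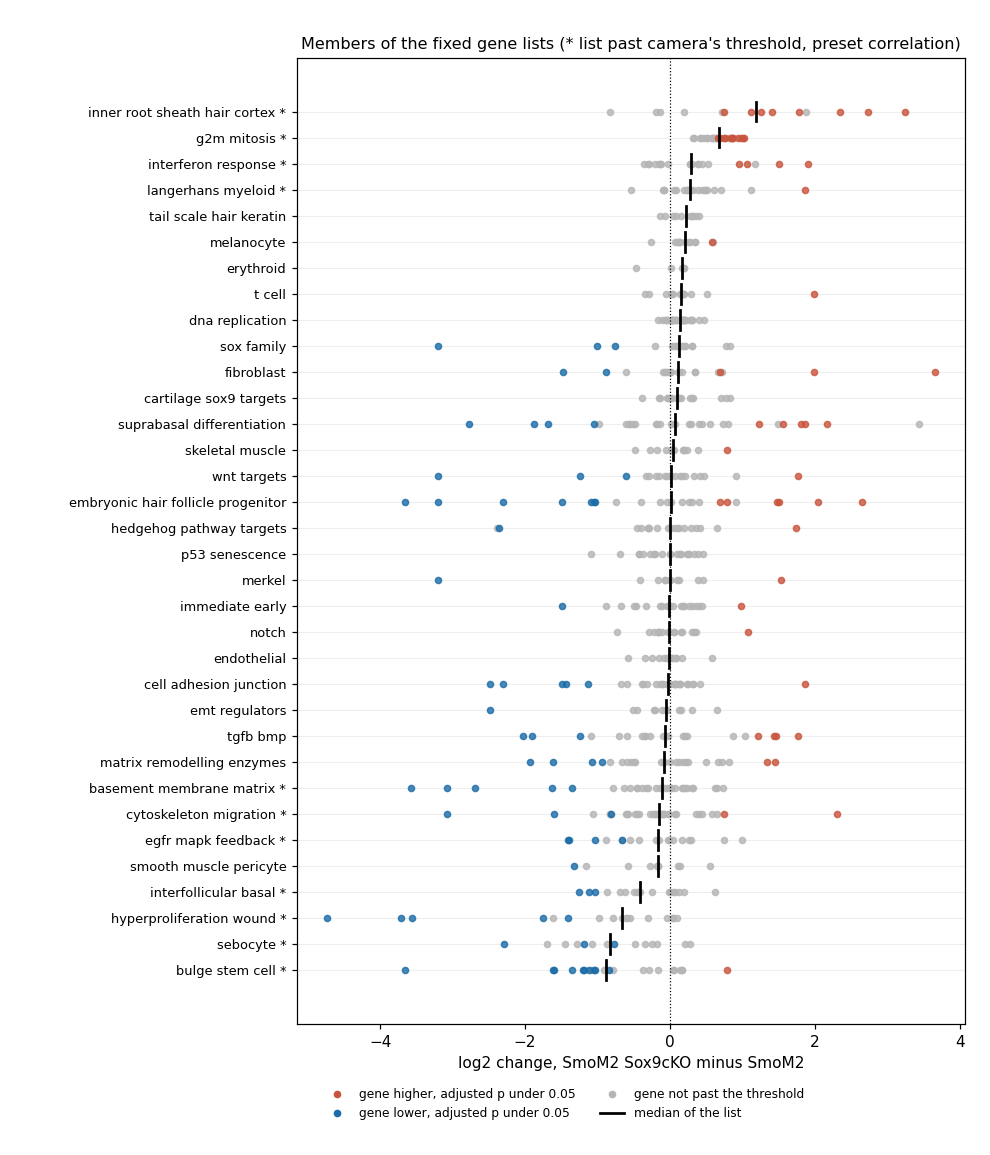
Log2 change, Sox9cKO minus SmoM2 (horizontal axis), of every measured member of the 34 fixed gene lists that were tested, with 1 point per gene (red higher, blue lower, grey not past an adjusted p of 0.05) and a black bar at each list's median; no error is drawn. The inner root sheath and hair cortex list has the highest median, 1.18, and the bulge list the lowest, -0.88, and asterisks mark the 11 lists that camera called with a preset correlation.

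Over all 34 lists tested, camera with its preset correlation called 4 higher and 7 lower. None was called with an estimated correlation (1 list had an unadjusted p under 0.05, and the lowest adjusted p was 0.726), and none by fry, which asks whether the genes of a list move one way on balance (7 had an unadjusted p under 0.05, and the lowest adjusted p was 0.192).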

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

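The test of these probe sets was chosen after the table was seen. Probe sets with no gene symbol or several in the annotation used here stood outside the gene comparison, and some of them carried signal that differed between the genotypes. Of 10092 such probe sets, 75 were called higher and 173 lower in Sox9cKO (limma, adjusted p under 0.05 over these probe sets). The highest increase among the called ones was 3.88 on the log2 scale (SE 0.36, adjusted p = 0.00368), a 14.7-fold difference, and the largest decrease was -5.29 (SE 0.23, adjusted p = 0.000480), from 9.78 ± 0.07 in SmoM2 to 4.49 ± 0.51 in Sox9cKO (SD, n = 2). For both, the arrays of the genotypes did not overlap. No biological explanation was tested for these probe sets.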

How the results depend on the processing

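The share of called genes per list (Fisher's exact test) and camera with an estimated correlation where arrays or dim genes were left out or every probe set was tested were added after the data were seen; all other alternatives were planned. Of the 115 named genes, 106 were called, and 33 lost the call without SmoM2 replicate 2, 26 without SmoM2 replicate 1, 12 without Sox9cKO replicate 1 and 14 without Sox9cKO replicate 2. These counts flatter the result, because 12 further genes were taken out of the text after the results were seen, some of them because they lost calls: of the 10 called among them, 8, 8, 3 and 3 lost the call without these arrays in turn. Of all 1126 called genes, 43.9% kept the call without SmoM2 replicate 2, 47.9% without SmoM2 replicate 1, 64.4% without Sox9cKO replicate 1 and 64.7% without Sox9cKO replicate 2. Under the alternatives that kept all 4 arrays at most 9 named genes lost a call and none turned direction, among those with a value there: 30 had none with dim genes left out and 3 had none without _x_at and _s_at probe sets. The 9 lost it with every probe set (Adamts1, Cdh11, Col6a3, Dusp5, Elovl5, Myc, Oca2, Palld and Spink5). Palld, Dusp5 and Elovl5 lost theirs with equal medians (adjusted p = 0.0508, 0.0504 and 0.0521), and these and Oca2 after quantile normalization (adjusted p = 0.0530, 0.0516, 0.0544 and 0.0544). The replicate block changed 2 named genes to called, Hhip (adjusted p = 2.58e-06) and Krt16 (adjusted p = 0.0420), and no list call. It raised the count of called genes to 1919 (879 higher, 1040 lower) and the Sox9 gene value, -0.75, to adjusted p = 0.00653. The labels name no shared batch, and the deviations of same-numbered arrays from their group means correlated at 0.0923 over genes. With 2 arrays per group the deviations of replicate 2 mirror those of replicate 1, so the 2 pairs give 1 comparison. Spiked RNA, 18S rRNA and the Actb difference were nevertheless lower in replicate 2 of both genotypes, so a shared batch is neither shown nor excluded.

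With 1 array left out, 534 to 900 genes were called (199 to 404 higher, 335 to 502 lower), because fewer samples remained, and 6 to 15 lists. A 1.5-fold minimum gave 1715 non-overlapping genes. With dim genes left out there were 452 such genes and 7 lists, since fewer genes entered. camera with an estimated correlation and fry called 0 lists each, and the mean of the probe sets put Sox9 at -1.68, whose cause was the probe sets averaged. The count of called genes stayed within 1.5 times of 1126 under the other alternatives: 1015 with the mean of the probe sets, 1102 with every probe set, 1071 without _x_at and _s_at probe sets, 801 with dim genes left out, 1022 after quantile normalization, 1105 with equal medians and 1149 with trend and robust prior. The higher share lay between 37.3% and 45.8%.

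For lists that were not called the direction of the test turned under some alternatives, while the median often kept its sign, and the cause was not tested. The medians under these were -0.0124 (mean of the probe sets), -0.0309 (every probe set) and 0.16 (quantile normalization) for erythroid genes, 0.00737 for endothelium, 0.11 for the Sox family, -0.0222 for TGF-beta and BMP and -0.0202 for Wnt targets with every probe set, 0.21 for matrix remodelling enzymes and 0.0527 for p53 with dim genes left out, and, equal to the medians without the block, 0.12 for the Sox family under the replicate block and 0.0167 for embryonic hair follicle progenitors by fry. Leaving out each array gave 0.00874 to 0.12 for embryonic hair follicle progenitors, 0.0223 to 0.13 for erythroid genes, -0.22 to 0.16 for Hedgehog, -0.0224 to 0.0212 for immediate early genes, -0.11 to 0.0692 for Merkel cells, -0.0628 to 0.0762 for Notch, -0.0709 to 0.0348 for p53, 0.0871 to 0.18 for the Sox family, -0.0211 to 0.26 for suprabasal differentiation and -0.0440 to 0.10 for Wnt targets. Genes near 3.23 to 3.62, the signal of absent Y-linked transcripts, cannot be read as lower still.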

Other observations

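The tests of the fibroblast, sebaceous and basal cell explanations were chosen after the results were seen, and those of genetic background, chromosome segment and copy number were not. Apart from the sebocyte, inner root sheath and fibroblast lists, the lists of other cell types held few calls by limma. In the Merkel cell list Snap25, a synaptic gene, rose by 1.53 (0.81 with the mean of its probe sets) and Sox2 fell by 3.20 (12 measured; camera adjusted p = 0.940). The melanocyte list had a median of 0.20 and camera adjusted p = 0.0640. Leaving out SmoM2 replicate 1 or 2 gave medians of 0.28 and 0.15, and leaving out Sox9cKO replicate 1 or 2 gave 0.36 and 0.03. Melanocyte genes had 1 call of 13, Oca2 (0.58, adjusted p = 0.0490), which was lost without each of the arrays in turn. T cell genes had 1 of 16 (Thy1; camera adjusted p = 0.177, and 0.0448 with every probe set, against 0.562 with an estimated correlation), skeletal muscle 1 of 14 (Myh2, 0.78; camera adjusted p = 0.656), smooth muscle and pericytes 1 of 11 (Cspg4, -1.32; camera adjusted p = 0.126), endothelium 0 of 15 (camera adjusted p = 0.729) and erythroid cells 0 of 5 (camera adjusted p = 0.940). Adjusted over the list alone, the counts of these 7 lists were the same, with 1 further higher gene in the smooth muscle and pericyte list. Myh2 was at adjusted p = 0.132, 0.107 and 0.105 without SmoM2 replicate 1, SmoM2 replicate 2 and Sox9cKO replicate 2. The other splits of the 4 arrays called 0 genes by limma when set by replicate number (377 at an unadjusted p under 0.05) and 0 when set by Y-linked signal (156), against 1126 by genotype, though 3 splits are too few for a share under 0.05. In those other splits each group held both genotypes, so the genotype difference entered the spread within groups and held calls down. Their counts of 0 are therefore no measure of false calls.

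Dcn, Thy1 and Col6a3, genes of fibroblasts, rose in Sox9cKO. Carry-over of fibroblasts into the sort would raise the other fibroblast genes too, yet the median change of the other 16 members of the list was 0.00262 (95% bootstrap interval over genes -0.07 to 0.18), below the smallest of the 3 changes, 0.70. Col1a1, Lum and Col3a1 changed by -0.02, -0.07 and 0.17, and Col1a2 by 0.72 (95% interval 0.01 to 1.42), which goes with carry-over. Dcn, Thy1 and Col6a3 were picked because they rose, so the rest of the list lying below them was largely fixed in advance. The median signal of the 16 in Sox9cKO was also only 4.59, so their probes may respond little. Carry-over is therefore neither shown nor excluded. A change of expression in the sorted cells was not tested.

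Sebocyte genes fell while inner root sheath genes rose. The sebocyte median without SmoM2 replicate 1 was -0.43 (95% bootstrap interval over genes -0.91 to -0.07), against -0.82 with all arrays. This interval measures the spread between genes, and a single SmoM2 array remained. More sebaceous cells in SmoM2 replicate 1 therefore cannot be told apart from other causes. A lower share of basal keratinocytes would raise the markers of other cell types alike, but the medians of the inner root sheath and sebocyte lists differed by 2.01 (95% bootstrap interval over genes 0.94 to 2.88). These lists were picked because they moved in opposite directions, so a clear difference was fixed in advance and decides nothing on that share. By itself a lower share would raise the sebocyte genes, which fell, but it could still add to the rise of inner root sheath genes. The basal list itself fell (median -0.42). A changed mix of cell types within the sort and an effect of Sox9 loss on the cells stay open and untested.

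Ifi202b, a gene whose level differs between inbred strains, fell by 2.99 (SE 0.24, adjusted p = 0.000831). In a panel of other strain-variable genes 2 of 6 were called, Glo1 (-1.51, adjusted p = 0.00221) and Alad (-0.87, adjusted p = 0.0198), more than among all genes (Fisher's exact test, one-sided p = 0.0486). Of the rest, Nnt changed by 0.05, Wdfy1 by -0.58 (adjusted p = 0.0531), Pttg1 by 0.66 (adjusted p = 0.165) and Erdr1 by 0.83 (adjusted p = 0.106). A difference of genetic background between the groups may therefore contribute to some calls, and the genotypes of the mice are not analysed here. Of the 200 measured genes nearest to Sox9, 13 were called (6.50%, 95% Clopper-Pearson interval 3.51% to 10.9%, against 6.19% of other genes, Fisher's exact test, one-sided p = 0.469). This interval is too wide to decide on a chromosome segment around Sox9. Ifi202b, Glo1 and Alad were not among those 13 genes, so the share does not bear on their calls. The gene beside Glo1, Btbd9, changed by -0.0271 and that beside Alad, Hdhd3, by -0.45 (95% interval -0.77 to -0.12). As these neighbours disagree, a copy number difference cannot be told apart from other causes at Glo1 and Alad.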
